A study of Mus musculus with 6 samples.

How the data were processed

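Total RNA of 6 samples of the mouse podocyte line MPC5 in high glucose was extracted with TRIzol, and libraries were made with the VAHTS Universal V6 kit, per the labels' protocols. The deposited table holds raw read counts per gene, with 1 column per library and no pooling. Reads were trimmed with fastp, aligned with HISAT and counted with HTSeq on GRCm39, per the submitters' processing notes. Tool versions, the annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes can therefore not be told apart, and genes with near-identical copies are uncertain. Whether an edit of Setdb2 removes its RNA, and which part of the gene was edited, is not given either.

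The table has 21719 genes, 16383 protein-coding and 5336 non-coding by its own annotation, and 0 of them had a count of 0 in every library. Columns were matched to samples by the genotype and number in their names, and 0 columns stayed unmatched. Entrez IDs were looked up in a gene table of the GRCm38 assembly, where 97.1% were found, for chromosome membership, older symbols, and the GC content and length of transcripts. No coordinates are printed because that build differs from the authors' own. Of 1149 genes in 39 lists, 1090 were found in the table.

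The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the counts, with TMM normalization, filterByExpr at its default minimum count of 10, genotype as the only term, and Benjamini-Hochberg adjustment over all genes tested at an adjusted p of 0.05. Fold changes are those of that fit, whose prior count is 0.125. CPM values are scaled by the TMM factors, with the SD over 3 libraries, and SE is the standard error of the log2 fold change. Gene lists with at least 5 tested genes and chromosomes with at least 100 were tested with limma's camera (limma 3.58.1) on voom values at a preset correlation of 0.01, two-sided, with adjustment over lists or chromosomes. The counts behind these values came to 36461449 to 37129174 reads per library, so genes with a few reads per library carry wide counting error. Exact intervals of ratios of summed reads are Clopper-Pearson at 95%, scaled by library size, and cover counting error only. Every pair of libraries in a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.55 to 2.71 in the libraries labelled Setdb2WT and 4.38 to 15.7 in those labelled Setdb2KO, so no pair was treated as repeat deposits of the same library; separate preparations of the same culture would differ in this way too.

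Lists, tests and alternatives were fixed before the data were examined, unless said otherwise. Named genes were, first, Setdb2 and Smad3. Next came the 10 protein-coding genes with the largest log2 fold change in each direction that passed the test, had a mean CPM of at least 5 and no overlap between the groups, leaving out bare model names. From each list came the members with the smallest adjusted p under 0.05 and a mean CPM of at least 1, up to 4 from lists that camera called, study lists and the podocyte list, and up to 2 from others. Some genes that this rule takes are not reported here.

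Simulated counts for the same design, with 200 genes changed among 12711 tested, were used to test the scripts before use. Of 50 genes per fold, edgeR recovered 31 at 1.2-fold, 43 at 1.5-fold, 48 at 2-fold and 49 at 4-fold with the right sign, and called 13 unchanged genes. Changed genes were drawn only from those above a minimum expected count, and equally in both directions. These rates therefore do not carry over to genes with few reads or to a change across most genes. Alternatives were DESeq2's size factors, upper-quartile and total-count scaling, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, no filter, a filter of CPM at least 1 in at least 3 libraries, the replicate number as a block, each library left out, camera with an estimated correlation, fry, glmTreat and an offset for GC content and length.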

Results

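RNA was sequenced from MPC5 cells, a conditionally immortalised mouse podocyte line, kept in high glucose. The 6 libraries formed 2 groups of 3, labelled Setdb2WT and Setdb2KO. The comparison asks which transcripts differ between these labels. Setdb2 is a SET-domain protein assigned to methylation of histone H3 lysine 9, and the title of the series names Smad3, a transducer of TGF-beta signals, as a gene it silences. Total counts lay between 36461449 and 37129174 reads per library. Genes with at least 1 read numbered 17181 to 17252 in the libraries labelled Setdb2WT and 17852 to 17926 in those labelled Setdb2KO. The log2 CPM correlation was at least 0.994 within a group and 0.906 to 0.909 between the groups. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

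The targeted gene was not lower in the libraries labelled Setdb2KO. Setdb2 (Entrez 239122, on chromosome 14 in GRCm38) had 12, 10 and 9 reads in the libraries labelled Setdb2WT and 17, 15 and 25 in those labelled Setdb2KO. This is 0.295 ± 0.043 CPM against 0.493 ± 0.14 CPM (SD, n = 3 each), by edgeR's model, with a log2 fold change of 0.73 (SE 0.38; 95% interval -0.095 to 1.56). It did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.088); under total-count scaling alone it passed, at an adjusted p of 0.043. Over the summed reads the ratio was 1.67, with an exact 95% interval of 1.06 to 2.67 that covers counting error only. Because the targeted gene was not lower in the libraries labelled Setdb2KO, the groups are called by their labels throughout. Each direction is that of the libraries labelled Setdb2KO against those labelled Setdb2WT.

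Smad3 (Entrez 17127, on chromosome 9 in GRCm38) fell 2.62-fold, from 162 ± 3.1 CPM in the libraries labelled Setdb2WT to 61.9 ± 2.9 CPM in those labelled Setdb2KO (SD, n = 3 each). Its counts were 5786, 5641 and 5578 against 2361, 2520 and 2286. The log2 fold change was -1.39 (SE 0.04; adjusted p = 3.8e-13, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). This direction is opposite to the rise that loss of the silencing named in the title would give. If the group labels were exchanged, the directions of Setdb2 and Smad3 would both turn.

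**Figure D1:**
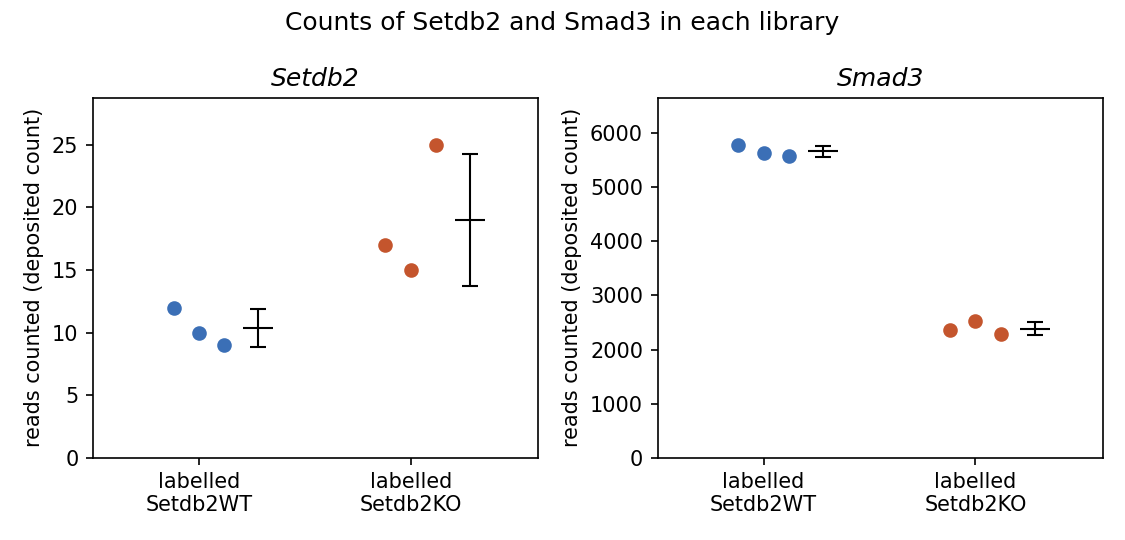
Deposited read counts (vertical axes, from 0) of Setdb2 and Smad3 in each of the 6 libraries, with points for libraries and black bars for the mean ± SD of each group of 3. The libraries labelled Setdb2KO held 15 to 25 Setdb2 reads against 9 to 12 in those labelled Setdb2WT, and 2286 to 2520 Smad3 reads against 5578 to 5786.

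The groups differed across most of the transcriptome. Of 13509 genes tested, 11318 (83.8%) changed between the libraries labelled Setdb2WT and those labelled Setdb2KO, 5607 higher and 5711 lower in the latter, by edgeR's quasi-likelihood test. At least 2-fold changes numbered 4409, with 2215 higher and 2194 lower, and 1551 genes changed at least 4-fold. Among 1194 non-coding genes tested, 654 rose and 213 fell. Non-coding genes held 0.70% to 0.73% of reads in the libraries labelled Setdb2WT and 1.14% to 1.21% in those labelled Setdb2KO. Whether RNA or library make-up underlies this was not tested. The 3 libraries of each group lay on opposite sides without overlap in 84.6% of the genes tested. For a given gene chance gives 10%, but genes of a library can shift together, so this share is not a test against chance. Against a limit of 1.5-fold instead of no change, glmTreat called 6137 genes. In every gene taken by the naming rule that passed the test, except Cd68, all 3 libraries labelled Setdb2KO lay on the same side of all 3 labelled Setdb2WT. The rule itself required this of the largest changes and took list members by the smallest adjusted p. It held for 11116 of all 11318 changed genes.

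Among protein-coding genes with a mean CPM of at least 5, the 10 largest rises in the libraries labelled Setdb2KO included 2 genes tied to lysosomes and nutrient sensing. Rragd, a Rag GTPase that signals amino acid supply to mTORC1, rose 107-fold from 0.133 ± 0.016 to 14.6 ± 0.54 CPM (SD, n = 3 each). Gpnmb, a glycoprotein of lysosomes and melanosomes, rose 98.9-fold from 0.295 ± 0.16 to 29.5 ± 2.0 CPM. The largest fitted rise was that of Myo15a, an unconventional myosin of hair cells (158-fold, log2 fold change 7.30, SE 0.17). Slc23a3 rose 113-fold, and Catsperd, a subunit of the sperm calcium channel, 94.2-fold. Col11a2, which encodes a fibrillar collagen chain, rose from 0.961 ± 0.17 to 72.4 ± 1.6 CPM, a 75.0-fold change. Gzmm, Nlgn3, Trnp1 and Iqcn rose 40.2-fold, 37.7-fold, 28.9-fold and 28.5-fold. Adjusted p over these 10 genes ran from 4.5e-16 to 4.1e-11 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The lower level rested on few reads, such as 12 Myo15a reads over 3 libraries, which gave a ratio of summed reads of 163 (exact 95% interval 93.0 to 316, counting error only).

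Under the same limits, the largest falls were those of Tmem252 and Sult1d1, a cytosolic sulfotransferase. Tmem252 had 1067 reads over the libraries labelled Setdb2WT and 6 over those labelled Setdb2KO, a ratio of summed reads of 196 with an exact 95% interval of 89.8 to 535. Sult1d1 fell 112-fold, from 126 ± 3.2 to 1.12 ± 0.19 CPM (SD, n = 3 each). Atoh8, a basic helix-loop-helix transcription factor, fell 82.1-fold, and Ntm, a neural cell adhesion protein, 73.0-fold. Eya2, a transcriptional coactivator with phosphatase activity, fell 49.0-fold from 17.1 ± 1.1 to 0.345 ± 0.065 CPM. Septin4 fell 41.8-fold, Dkk3, a secreted protein of the Dickkopf family, 38.0-fold, and ccdc198 36.9-fold. Rbm47, an RNA-binding protein, and Ctxnd1 fell 31.4-fold and 29.6-fold. Adjusted p ran from 1e-16 to 5.6e-12 in edgeR's quasi-likelihood test.

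All 25 tested genes of the cholesterol synthesis list fell in the libraries labelled Setdb2KO, 23 of them at least 2-fold, with a median log2 fold change of -2.52. Sqle, which oxidises squalene, fell 10.1-fold from 512 ± 2.1 to 50.6 ± 2.0 CPM (SD, n = 3 each). Cyp51, which removes a methyl group from lanosterol, fell 7.48-fold from 605 ± 5.4 to 80.9 ± 2.5 CPM. Camera with a preset correlation of 0.01 placed the list below the other genes tested at an adjusted p of 3.4e-12, against an adjusted p = 0.102 with an estimated correlation.

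Genes of autophagy and the lysosome moved the other way. Of 36 tested, 27 rose, 5 fell and 4 did not pass, with a median log2 fold change of 1.05, against 30 higher and 2 lower under total-count scaling. Hexa, a lysosomal hexosaminidase subunit, rose 7.70-fold from 36.1 ± 1.2 to 278 ± 6.3 CPM (SD, n = 3 each), and Atp6v0d1, part of the proton pump that acidifies lysosomes, rose 6.43-fold. The membrane protein Lamp1 rose 3.62-fold, and Map1lc3b, which coats autophagosomes, 3.48-fold. It was the only list that camera placed higher (adjusted p = 4.3e-07; adjusted p = 0.415 with an estimated correlation). Atp6ap2, an accessory subunit of the same pump and a receptor for prorenin, rose 5.78-fold, and Ece1, which activates endothelin, fell 1.52-fold. They belong to a list of renin-angiotensin and endothelin genes with 4 tested members, 2 higher and 2 lower, too few for camera.

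Glycolytic and antioxidant genes were mostly lower in the libraries labelled Setdb2KO. Of 25 glycolysis and glucose uptake genes 19 fell, 5 rose and 1 did not pass, with a median log2 fold change of -1.10. Pfkl, a phosphofructokinase subunit, fell 8.87-fold, Pdk1, which inhibits pyruvate dehydrogenase, 11.7-fold, and Gpi1 3.58-fold. Ldha, which reduces pyruvate to lactate, fell 4.36-fold, a value that reads shared with processed copies leave uncertain. Camera gave this list an adjusted p of 5.9e-04, and an adjusted p = 0.415 with an estimated correlation. Of 31 NRF2 and oxidative stress genes 25 fell and 5 rose, with a median of -1.29 (camera adjusted p = 2.9e-05; adjusted p = 0.109 with an estimated correlation). Gclc, which limits glutathione synthesis, fell 7.24-fold, and the glutathione transferase Gsta4 18.2-fold from 81.0 ± 0.62 to 4.46 ± 0.091 CPM (SD, n = 3 each). Gstm1, which has near-identical relatives and is uncertain for that reason, fell 6.55-fold. G6pdx and Pgd, enzymes of the pentose phosphate pathway, fell 5.78-fold and 10.3-fold.

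The matrix and cytoskeleton lists were lower as well. Of 41 tested genes of the extracellular matrix and basement membrane, 30 fell, 8 rose and 3 did not pass, with a median log2 fold change of -0.96 (camera adjusted p = 2.9e-04; adjusted p = 0.415 with an estimated correlation). Thbs1, a matrix glycoprotein that activates latent TGF-beta, fell 4.47-fold. The collagen genes Col6a1 and Col18a1 fell 7.29-fold and 3.69-fold, and Sparc, a collagen-binding protein, fell 4.74-fold. Among 52 genes of the actin cytoskeleton and focal adhesions 35 fell, 11 rose and 6 did not pass, with a median of -0.42 (camera adjusted p = 2.9e-04; adjusted p = 0.415 with an estimated correlation), against 31 lower and 15 higher with a median of -0.26 under total-count scaling. The actin cross-linker Flna fell 2.73-fold, Tagln2 3.05-fold and Ezr, which ties actin to the membrane, 3.17-fold. Actg1, whose reads processed copies share, fell 2.40-fold. Among 28 matrix proteases and inhibitors 16 fell and 8 rose (camera adjusted p = 0.271). Timp3, an inhibitor of matrix proteases, rose 3.75-fold, and Timp2 and Mmp14 fell 1.97-fold and 2.88-fold.

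Among the TGF-beta lists, receptors and transducers moved in both directions. Of 39 tested components of TGF-beta and BMP signalling 17 rose, 14 fell and 8 did not pass (camera adjusted p = 0.979). Besides Smad3, the libraries labelled Setdb2KO had 6.38-fold less Ltbp1, which stores latent TGF-beta in the matrix, 2.62-fold less Smurf1, a ubiquitin ligase for receptors and Smads, and 2.35-fold less Tgfbr2, the type II receptor. The median and mean of this list and camera were positive while fry's direction was down. Of 42 TGF-beta response genes 26 fell and 16 rose, with a median of -0.86 (camera adjusted p = 0.173, not past the threshold). Id3, an inhibitor of basic helix-loop-helix factors, fell 11.3-fold, and Ccn2, a matricellular protein, 2.99-fold from 651 ± 1.9 to 217 ± 7.2 CPM (SD, n = 3 each). Timp3 and Thbs1 belong to this list too, the former 3.75-fold higher and the latter 4.47-fold lower.

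Podocyte genes were more often lower than higher in the libraries labelled Setdb2KO. Of 33 tested 21 fell, 10 rose and 2 did not pass, with a median log2 fold change of -0.54. Npnt, a ligand in the glomerular basement membrane, fell from 93.1 ± 1.3 to 4.90 ± 0.18 CPM (SD, n = 3 each; log2 fold change -4.25), and Podxl, the charged coat protein of foot processes, 10.2-fold. Inf2, an actin-regulating formin, fell 3.80-fold, and Dag1, dystroglycan, 2.70-fold. Camera did not call the list (adjusted p = 0.0596), but did so among genes with a CPM of at least 1 in at least 3 libraries (adjusted p = 0.0372). Over all genes tested the list had an adjusted p = 0.415 with an estimated correlation. Nphs1, Trpc6, Ptpro and Tcf21 were not analysed here.

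Markers of other kidney cell types also differed between the groups. Of 7 parietal epithelium genes 6 fell and 1 rose, with a median of -1.33 (camera adjusted p = 0.0177; adjusted p = 0.415 with an estimated correlation). Cd24a fell 4.49-fold, the scaffold protein Akap12 3.96-fold, Pax2, a kidney lineage transcription factor, 2.24-fold and Cldn1, a tight junction protein, 3.07-fold. Of 11 mesangial genes 7 fell and 2 rose (camera adjusted p = 0.142), with Tagln 6.04-fold and Ptn 16.6-fold lower. Of 7 tubular genes 4 fell and 3 rose (camera adjusted p = 0.651), including Aqp1, the water channel, which fell 9.05-fold from 468 ± 3.1 to 51.7 ± 1.8 CPM (SD, n = 3 each), and Cdh16, a kidney cadherin, which fell 1.71-fold. Of 7 endothelial genes 4 fell and 3 rose (camera adjusted p = 0.979), and the median was negative while the mean was positive. Esam rose 6.47-fold, but at a low level, from 0.266 ± 0.086 to 1.74 ± 0.26 CPM (SD, n = 3 each), and Ehd3 fell 1.93-fold. All 4 tested fibroblast genes fell, Vim 3.81-fold and Gsn 3.53-fold. Of 3 tested immune genes Csf1r fell 1.86-fold, and Cd68 rose 1.25-fold at an adjusted p of 0.049 in edgeR's test, with overlapping libraries. The fibroblast and immune lists were too small for camera, though the fibroblast list reached 5 tested genes when any library but Setdb2WT replicate 2 was left out and was then called at the preset correlation (adjusted p 0.0171 to 0.0200; an estimated correlation was not run for it).

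Ribosomal protein genes shifted a little, mostly downward, in the libraries labelled Setdb2KO. Of 47 tested 45 fell, 1 rose and 1 did not pass, with a median log2 fold change of -0.44 (camera adjusted p = 1.2e-08; adjusted p = 0.463 with an estimated correlation), against 37 lower and 2 higher with a median of -0.29 under total-count scaling. Rps2, Rplp0 and Rpl22 fell 3.24-fold, 1.77-fold and 1.99-fold, values that reads shared with processed pseudogenes leave uncertain. Of 13 mitochondrially encoded genes 4 rose and 2 fell (camera adjusted p = 0.883), against 7 higher and 0 lower under total-count scaling and 5 and 1 with DESeq2's size factors. ND4 rose 1.10-fold and ND1 fell 1.23-fold, but ND1 did not pass under total-count scaling. Of 29 immediate early and heat shock genes 18 rose and 10 fell (camera adjusted p = 0.144), against 19 higher and 5 lower under total-count scaling. The stress-induced transcription factor Atf3 rose 3.77-fold, and Hspa8, a constitutive chaperone with many processed copies, fell 6.53-fold from 2016 ± 27 to 309 ± 13 CPM (SD, n = 3 each). Of 17 replication-dependent histone genes, a family of near-identical copies, 8 rose and 4 fell (camera adjusted p = 0.417). H4c12 rose 5.15-fold and H1f5 7.46-fold, both at a low level, from 0.619 to 3.20 CPM and from 0.276 to 2.08 CPM.

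Of 19 senescence genes and CDK inhibitors 16 fell and 2 rose, with a median of -0.54 (camera adjusted p = 0.0177; adjusted p = 0.415 with an estimated correlation). Cdkn1a, an inhibitor of cell division, rose 2.82-fold, and Lmnb1, a nuclear lamina protein that senescent cells lose, fell 1.71-fold. Gdf15, a secreted stress cytokine, fell 2.04-fold. Of 35 DNA replication genes 20 fell and 11 rose (camera adjusted p = 0.180), against 15 lower and 14 higher under total-count scaling, with Tk1 5.18-fold and Rrm2 5.68-fold lower, both enzymes of nucleotide supply. Of 37 mitosis genes 19 fell and 15 rose, with a median of -0.13 that turned to 0.029, with 13 lower and 18 higher, under total-count scaling (camera adjusted p = 0.925), and Ccnb2 and Kif23 fell 4.27-fold and 1.98-fold. Of 30 unfolded protein response genes 14 fell and 13 rose, with a median of -0.050 that turned to 0.10 under total-count scaling (camera adjusted p = 0.925, direction down) and a positive mean. Pdia6, a chaperone of the endoplasmic reticulum, fell 4.82-fold, whereas Ddit3, a transcription factor of the stress response, rose 7.90-fold from 20.3 ± 1.6 to 160 ± 2.1 CPM (SD, n = 3 each). Of 39 apoptosis and p53 target genes 17 rose and 19 fell, with a median of -0.087 that turned to 0.067 under total-count scaling and a positive mean (camera adjusted p = 0.979, direction up), and Sesn2 and Gadd45b rose 5.53-fold and 4.74-fold.

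The chromatin list was called neither way. Of 27 tested SET-domain and H3K9 methyltransferase genes and their partners 13 rose, 5 fell and 9 did not pass, Setdb2 among them (camera adjusted p = 0.353). Under total-count scaling 19 were higher and 5 lower. Kdm3a and Kdm4c, demethylases of H3 lysine 9, rose 2.35-fold and 2.39-fold. Uhrf1, which guides maintenance DNA methylation, and Trim28, a corepressor that recruits H3K9 methyltransferases, fell 2.30-fold and 1.82-fold. Of 6 tested germline genes 4 rose and 2 fell (camera adjusted p = 0.631), with Ddx4, a germ cell helicase, rising from 0.133 ± 0.092 to 2.02 ± 0.68 CPM (SD, n = 3 each) and Smc1b falling 1.39-fold. Of 14 imprinted genes 6 rose and 5 fell (camera adjusted p = 0.925, with fry down and the median positive), Igf2r 2.53-fold higher and Peg10 5.03-fold lower. Of 29 Hox genes 16 rose and 12 fell (camera adjusted p = 0.353), with Hoxc6 and Hoxb7 3.47-fold and 2.20-fold higher.

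Signalling and metabolic lists that camera did not call still held large changes of single genes. Notch1, a receptor, and Lfng, which modifies it, fell 7.53-fold and 11.9-fold among 22 Notch genes, of which 10 rose and 9 fell (camera adjusted p = 0.979, with a negative median, a positive mean and camera's direction up). Of 26 Wnt genes 16 fell and 6 rose (camera adjusted p = 0.142), with the receptor Fzd6 1.90-fold higher. Of 19 genes of the epithelial-to-mesenchymal transition 13 fell and 4 rose, with a median of -0.27 (camera adjusted p = 0.0545), and the calcium-binding protein S100a4 fell 5.52-fold. Under total-count scaling 9 were lower and 4 higher, with a median of -0.12. Camera called this list without Setdb2WT replicate 2 (adjusted p = 0.0379) or 3 (adjusted p = 0.0484) and without Setdb2KO replicate 1 (adjusted p = 0.0481). With all libraries it had an adjusted p = 0.415 with an estimated correlation. In the inflammation list 18 of 35 genes fell and 14 rose (camera adjusted p = 0.979), with the chemokine Cxcl5 4.40-fold lower and Tnfaip2 down from 104 ± 3.4 to 41.8 ± 1.1 CPM (SD, n = 3 each). Of 46 interferon-stimulated genes 17 fell and 14 rose (camera adjusted p = 0.979), with Samd9l 4.54-fold lower and Ifi27 2.33-fold higher. The interferon median of -0.051 and mean were negative while camera's direction was up, and the median turned to 0.10 under total-count scaling. Of 24 hypoxia genes 12 fell and 10 rose (camera adjusted p = 0.979), against 12 each way under total-count scaling, with P4ha1, a collagen prolyl hydroxylase, 2.81-fold lower. Of 17 polyol, hexosamine and glycation genes 10 fell and 5 rose (camera adjusted p = 0.353). Of 27 genes of fatty acid oxidation and PPAR targets 17 fell and 7 rose (camera adjusted p = 0.142), with Fabp5 8.24-fold and Acads 8.05-fold lower. Of 51 nuclear genes of the respiratory chain 30 fell and 13 rose (camera adjusted p = 0.142), none of them 2-fold, against 19 lower and 20 higher under total-count scaling, with Ndufb8 1.85-fold and Atp5a1 1.59-fold lower.

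**Figure D2:**
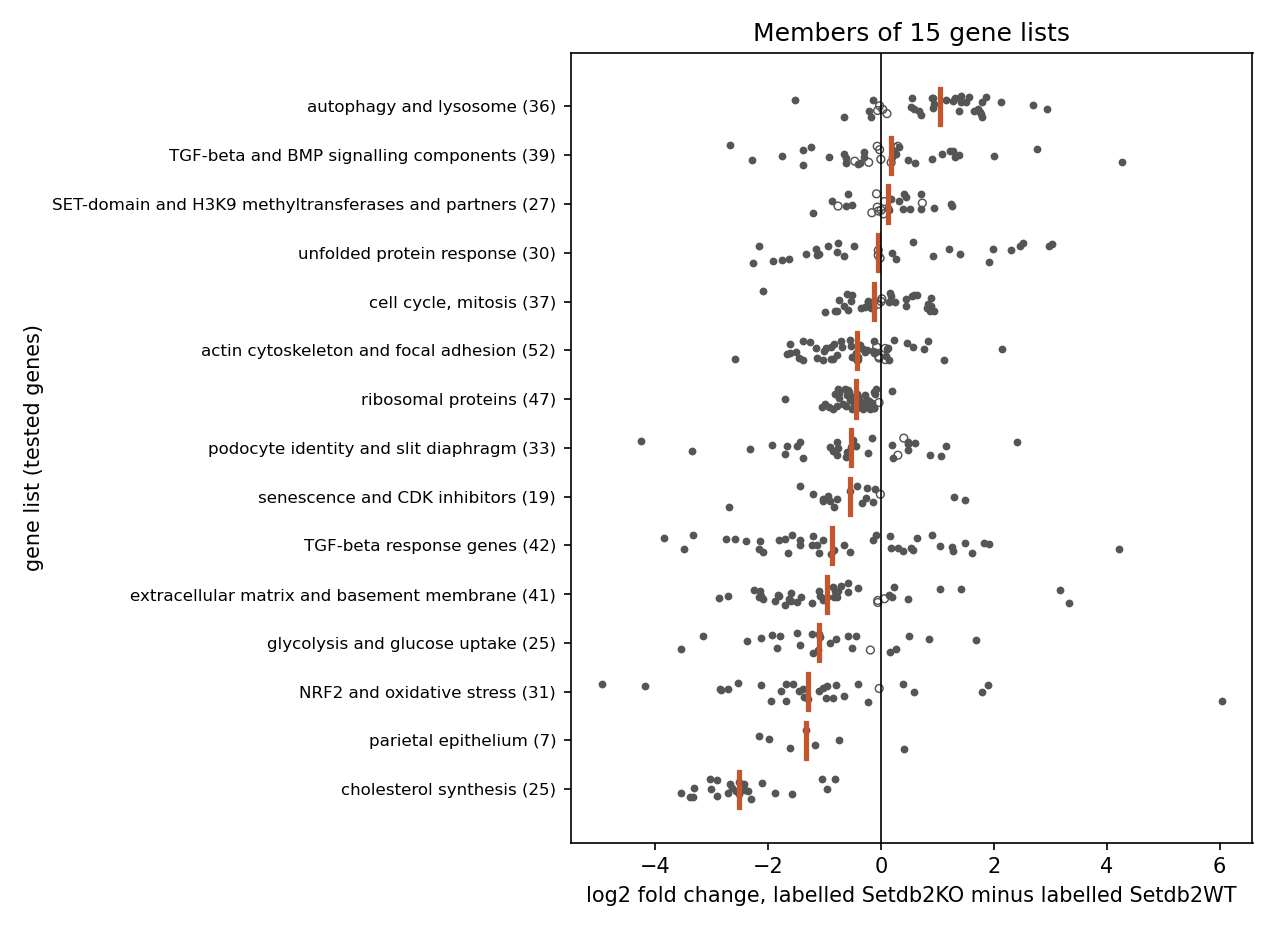
Log2 fold change, libraries labelled Setdb2KO minus those labelled Setdb2WT (horizontal axis), of the tested members of 15 gene lists (rows, with the number tested). Filled points passed edgeR's test, open points did not, and bars mark medians, which ran from -2.52 for cholesterol synthesis to 1.05 for autophagy and lysosome. The median of the mitosis and unfolded protein response lists turned positive under total-count scaling.

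Of 36 lists tested, camera with the preset correlation called 9, of which 1 was higher and 8 were lower in the libraries labelled Setdb2KO. With an estimated correlation it called 0 at an adjusted p under 0.05 and 2 at an unadjusted p under 0.05, and fry, which compares a list with no other genes, called 33. Counts adjusted over the list alone were the same as those over all genes tested, except 4 higher and 14 lower in the epithelial-to-mesenchymal list, 12 and 36 in the actin list, 18 and 19 in the apoptosis list and 13 and 17 in the interferon list. They were 2 and 1 in the mitochondrial list and 0 and 1 in the immune list. Of 20 chromosomes with at least 100 tested genes, camera called 0 with either correlation, 0 at an unadjusted p under 0.05, and fry called 19. Their median log2 fold changes lay between -0.13, on the X chromosome, and 0.11, on chromosome 17.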

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

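Total-count scaling, glmTreat and the offset for GC content and length were chosen after the data were seen. The count of genes changed stayed within 1.5 times the reported 11318 in every alternative except glmTreat, which tests against 1.5-fold and called 6137 genes, fewer by its construction. Other scalings, tests and filters gave 10380 to 12183, and leaving out a library 11067 to 11496. The reported 4409 changes of at least 2-fold ran from 3521, with the CPM filter, to 5419, with no filter, which differ in the genes tested. Total-count scaling moved the median log2 fold change of all genes to 0.16 and the split to 6550 higher and 4833 lower. Among lists, camera with an estimated correlation called 0 and fry called 33, where the preset correlation called 9; the cause was not tested.

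Replicate numbers did not pair the libraries: deviations of libraries that share a number correlated at -0.0063, -0.067 and 0.015 across genes. With the replicate block 11190 genes changed (5529 higher, 5661 lower). Of 1679 pairs of a named gene and a setting, 1670 kept direction and side of the threshold and 0 reversed. Cd68 missed the threshold in 7 settings, without Setdb2WT replicate 2 or 3 and without Setdb2KO replicate 1 or 2 among them (adjusted p 0.131 to 0.186), and ND1 missed it and Setdb2 passed it under total-count scaling. With 9 to 25 reads per library, depth limits what can be said of Setdb2.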

Other observations

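The tests on the direction of Setdb2 and Smad3, on the breadth of the change, on dividing cells, and on GC content and length were chosen after the results were seen. The lists of lysosomal, amino acid response and fatty acid genes were written after Rragd, Gpnmb and other genes of these kinds had been seen, hold no gene of the fixed lists, and left out the genes already seen. The pathway annotation deposited with the table was also tested only then.

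Fatty acid synthesis genes fell with the sterol genes in the libraries labelled Setdb2KO. Of 16 tested 14 fell and 2 rose, with a median log2 fold change of -1.37 (camera p = 1.8e-05; p = 0.0101 with an estimated correlation, by limma). Fads2, a fatty acid desaturase, fell 8.60-fold, Slc25a1, the mitochondrial citrate carrier, 7.04-fold, Acaca, which makes malonyl-CoA, 4.21-fold, and Acly 3.30-fold. Acacb rose 3.85-fold. As a hypothesis, a lower SREBP-type output may underlie the fall of both lipid lists, since the fatty acid median of -1.37 lay beyond the -0.5 set for it beforehand. That bound is not particular to such an output. Among the annotated pathways, Fatty acid degradation had a median of -0.82 (28 lower, 5 higher) and Glutathione metabolism -1.08 (33 lower, 6 higher). The annotated Fatty acid biosynthesis pathway had a median of -0.60 (11 lower, 1 higher). No protein or lipid was measured.

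Of 313 annotated pathways with 10 to 300 tested genes, camera with the preset correlation placed 5 higher and 47 lower. With an estimated correlation it called 0 at an adjusted p under 0.05 and 19 at an unadjusted p under 0.05. Lysosome had 72 genes higher and 31 lower of 112 (adjusted p = 0.0011; adjusted p = 0.555 with an estimated correlation). Steroid biosynthesis had 14 lower and 3 higher of 17, and Terpenoid backbone biosynthesis 16 lower and 4 higher of 21 (adjusted p = 0.0016 and 0.0082; adjusted p = 0.555 with an estimated correlation for both), so not all genes annotated to these pathways fell.

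Amino acid response genes leaned higher. Of 22 tested 15 rose and 6 fell (camera p = 0.0224; p = 0.419 with an estimated correlation, by limma). Nupr1, a stress-induced chromatin protein, rose 6.84-fold and Cebpg, a partner of ATF4, 3.27-fold, while the transporter Slc7a5 fell 1.76-fold. The median of 0.49 fell between the bounds of 0.2 and 0.5 set beforehand, so an ATF4-type response may or may not be at work, and this list does not decide it.

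Setdb2 was not lower and Smad3 was lower in the libraries labelled Setdb2KO. An exchange of single libraries is argued against by the highest correlation between groups, 0.909, which lay below the lowest within a group, 0.994. For the reads counted to Setdb2, too few to show a fall to 50% is argued against by the interval's lower end, -0.095 on the log2 scale, above -1. Reads of an overlapping or antisense gene cannot be told apart among these few. A fall of the Setdb2 transcript itself is therefore not excluded. Exchanged labels of both whole groups cannot be told apart from an edit that leaves the transcript in place. The Setdb2 log2 fold change of 0.73 fits either, and every comparison would only turn its sign. Smad3, with a log2 fold change of -1.39, fell where loss of the silencing named in the title would raise it. Exchanged labels would turn this direction too, but no value here tests the title, so Smad3 does not decide the question. An effect of the edit itself stays open too, as untested.

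The breadth of the change, 11318 genes, stayed at 11315 and 11383 under upper-quartile and total-count scaling. The lowest count of at least 2-fold changes under the other scalings was 4400 against 4409. These scalings moved the median log2 fold change of all genes to at most 0.16, too little to remove most 2-fold changes. A larger shift in RNA content is therefore not excluded. Total-count scaling did move the split, to 6550 genes higher and 4833 lower. Copy number of whole chromosomes is argued against by the chromosome medians, of which the farthest from 0 was -0.13. A difference between cultures other than the edit, such as clone, density or passage, cannot be told apart from genotype: the labels name no cultures, and the coefficient of variation within groups was 0.046. Genotype remains open on the same footing.

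Lysosomal genes rose while lipid synthesis genes fell. As a hypothesis, a TFEB/TFE3-type programme may take part: of 40 other lysosomal and nutrient-sensing genes 31 rose and 7 fell, with a median of 0.93 (camera p = 7.9e-08; p = 0.103 with an estimated correlation, by limma). Ctns, the lysosomal cystine exporter, rose 8.30-fold and Tpp1, a lysosomal peptidase, 4.52-fold, while Gusb fell 2.27-fold. GC content and length are argued against, as the median of the autophagy and lysosome list was 1.06 with their offset and 1.05 without. Whether fewer cells were dividing, with or without such a programme, is not decided here, since genes of both cell cycle lists went both ways. The mitosis median was -0.13 (SD over genes 0.65) with 19 genes lower and 15 higher, and with 1 lower and 0 higher at least 2-fold. By contrast, 20 DNA replication genes fell and 11 rose (15 and 14 under total-count scaling), with 7 lower and 0 higher at least 2-fold and a mean log2 fold change of -0.38. Tk1 and Rrm2 fell 5.18-fold and 5.68-fold, and Cdkn1a rose 2.82-fold. Ccnb2, the only mitosis gene at least 2-fold lower, fell 4.27-fold. What would drive such a programme was not tested, and culture and genotype both remain open.

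The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 11318 genes changed, 5607 higher, 5711 lower and 4409 changed at least 2-fold, each matched by 1 of the 10 splits, itself, with 0 as the highest other count. In the 9 other splits edgeR and limma-voom called 0 genes, and 4 to 31 genes had an unadjusted p under 0.05 in edgeR. Camera with the preset correlation called 9 lists in the real split and up to 10 in another, and 4 of the 10 splits called as many, so the number of list calls does not set the real split apart. Each of the other splits leaves part of the difference between the groups in place, since it puts 2 libraries of a label against 1. The same mixing widens the spread within each side, so calls of 0 genes there follow from the design. These splits therefore cannot show whether the gene counts of the real split exceed chance. Chromosomes gave 0 calls in the real split and in all 10 splits.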
